A study of Mus musculus with 4 samples.

How the data were processed

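RNA abundance was measured with Affymetrix MG-U74Av2 oligonucleotide arrays, named as the platform in the header of the probe table used here, on 4 samples of pooled aortic RNA from adult male C57BL/6J mice. The labels place 2 arrays in a rosiglitazone group (25 mg/kg per day for 21 days) and 2 in a vehicle group given vehicle over the same 21 days. The labels number the arrays 1 and 2 for rosiglitazone and 3 and 4 for vehicle. They do not say whether the arrays of a group came from separate pools of animals. So p-values of single probe sets measure the spread between these arrays, which may be technical. The number of mice per pool is not given in the sources used here.

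The deposited values are hybridisation intensities on a linear scale, 1 whole number per probe set and array. Neither the software nor the background correction that made them is given in the sources used here. The values themselves show a common scale: with 2% of the values trimmed at each end, the mean intensity was 1501 on each of the 4 arrays. Values ran from 2 to 616423, and the table used here holds no detection calls, so signal over background cannot be judged per probe set. Global scaling of this kind fixes the mean and not the median. If many abundant transcripts rise in a group, the intensities of the others are pushed down in it. Median intensities were 591 and 620 on the rosiglitazone arrays and 648 and 635 on the vehicle arrays, a largest gap of 0.13 on the log2 scale. This gap was under the limit of 0.2 set before the data were examined, so the deposited values entered the tests without further scaling.

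Of 12488 probe sets, 66 control probe sets were left out of the tests. Names came from the platform's probe table, with symbols looked up by gene identifier in a table of the GRCm38.p6 assembly that was used for names alone. Among the 12422 other probe sets, 10833 had 1 gene symbol, 396 had several and 1193 had none listed. The identifier was found for 10817 of them, and 0 symbols changed on updating. No gene was named from a probe set with several symbols. No coordinates are given, because no genome build is given in the sources used here.

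Intensities under 148, the 20th percentile of all values pooled, were set to 148 before log2 was taken. Probe sets were kept when their mean log2 intensity lay at or above the 40th percentile of all values, an intensity of 414, which left 7134 probe sets, 6393 of them with 1 symbol, for 5466 different genes. Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the 7134 probe sets and a threshold of 0.05 on the adjusted p. The model had 2 residual degrees of freedom per probe set and a median of 7.14 prior degrees of freedom borrowed across probe sets. Where both arrays of a group lay under the floor, the fold is a lower bound and is written as at least that fold. With 1 array at the floor the fold is pulled toward 0 as well. A group with both arrays under the floor has an SD of 0 by construction, so the standard error and p of such a probe set may be too small. A permutation of the array labels is of no use here, since 3 splits of 4 arrays into 2 and 2 give a smallest exact permutation p of 0.333.

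24 gene lists, covering the pathways and cell types that the tissue and the drug call for, were fixed before the data were examined. Each was tested with limma's camera, which compares the list with all other genes, at a preset inter-gene correlation of 0.01, on the brightest probe set of each gene, two-sided, with Benjamini-Hochberg adjustment over the 24 lists. Each list had at least 5 measured genes. At the preset correlation camera sets a list's shift against the spread over genes, so its p-values do not measure the spread between arrays. The same test with the correlation estimated from these arrays, and fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, were run as alternatives. List members were counted as past the threshold over all probe sets and adjusted over the list alone.

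Genes were named by a rule fixed before the data were examined. It takes, from probe sets with 1 symbol past the threshold and with no overlap between the groups, the 15 with the largest rise and the 15 with the largest fall. A direction with fewer than 12 is filled to 12 by the smallest unadjusted p among probe sets changed at least 1.5-fold with no overlap, and these are given as values. It adds Pparg and up to 4 members of each list. Other named genes were chosen after their values were seen, as is said where they appear.

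Simulated arrays had the real means, known changes and, as spread, residual SDs taken before the floor from probe sets of like intensity. The whole procedure was tested on these arrays. Over 20 simulations of 7134 probe sets it called 0.608% of probe sets changed by 1 on the log2 scale, 22.7% of those changed by 2 and 60.2% of those changed by 4, and 2.34% of its calls were false. It called 1 of 480 unshifted lists, and a list shifted by 0.5 was called in 20 of 20 simulations. The simulated probe sets varied independently, so these list figures do not cover correlated genes. Each SD rests on 2 residual degrees of freedom, so the simulated spreads carry sampling noise and the shares called may differ from those on the real arrays. The number of arrays limits the precision, and in the simulations changes of the size of 1 on the log2 scale were mostly missed.

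The alternatives tried were quantile normalisation, centring on each array's median, floors at the 5th and 40th percentiles, a pseudocount of 148 in place of the floor, no filter and a filter at the 60th percentile, eBayes without a trend or with a robust prior, leaving out each array in turn, other thresholds, 1 probe set per gene, the mean of a gene's probe sets, and the other splits of the arrays. Lists reduced to genes in no other fixed list were added after the data were seen.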

Results

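Gene expression was profiled in pooled aortic RNA of adult male C57BL/6J mice after 21 days of rosiglitazone, a thiazolidinedione drug that activates the nuclear receptor PPARγ, at 25 mg/kg per day, or after vehicle. There were 2 arrays per group. No sequencing depth applies to arrays, and their number limits the precision. Across the 7134 probe sets tested, log2 intensities correlated at 0.881 between the rosiglitazone arrays and at 0.892 between the vehicle arrays, against 0.855 to 0.866 between arrays of different groups, where genes are not independent replicates. The median SD between the 2 arrays of a group was 0.29 on the log2 scale for rosiglitazone and 0.25 for vehicle. The ratio of 3' to 5' actin signal, a measure of RNA integrity, was 7.74 and 9.62 on the rosiglitazone arrays and 8.88 and 11.9 on the vehicle arrays, with overlap between the groups. The same ratio for Gapdh was 8.79 and 10.8 with rosiglitazone and 11.1 and 11.1 with vehicle, higher on both vehicle arrays. On every array the 3' signal of each transcript was thus far above its 5' signal, by at least 7.74-fold. Overlap between the groups therefore does not show that the RNA was intact. The cause of this excess, and its effect on probe sets of the same gene that disagree, were not tested. The comparison of the groups asked which aortic transcripts differed after chronic treatment with the drug.

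The aortas of rosiglitazone-treated mice had far less transcript of several inflammatory genes than those given vehicle. Saa3, an acute-phase serum amyloid, fell at least 131-fold and Il1b, the cytokine interleukin 1 beta, at least 112-fold. S100a8 and S100a9, calcium-binding proteins abundant in neutrophils, fell 84.0-fold and 47.4-fold. In the other direction, Lipa, the lysosomal acid lipase, rose 10.8-fold, Cdkn1c, an inhibitor of cyclin-dependent kinases, rose 3.33-fold, and Fabp3, the heart-type fatty acid binding protein, rose 2.92-fold. In all, 26 of 7134 probe sets passed an adjusted p of 0.05 in limma, 3 higher and 23 lower with rosiglitazone, for 3 and 21 different genes. All 26 had no overlap between the groups, as did 2912 probe sets tested, or 40.8% where chance gives 33.3%. The count changed with the arrays used. With vehicle replicate 3 or vehicle replicate 4 left out 1 probe set passed, that of S100a9, whereas 47 passed without rosiglitazone replicate 1 and 78 without rosiglitazone replicate 2. No probe set (0) passed in limma when the filter on dim probe sets was dropped or the floor was raised to the 40th percentile, although 1202 and 933 of 12422 then had an unadjusted p under 0.05, against 776 of 7134. That floor equals the filter's intensity of 414, so it too let every probe set through.

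Saa3 had a log2 fold change of -7.04 with a standard error of 0.31 (limma, adjusted p = 9.5e-06). Its intensities were 20340 and 18570 on the vehicle arrays. Both rosiglitazone arrays lay under the floor of 148, which set their SD to 0. The same held for Il1b, at 18270 and 15030 with vehicle, and for Cxcl2, a chemokine that attracts neutrophils, at 14130 and 14230 with vehicle, which fell at least 95.8-fold. S100a8 had a mean log2 intensity of 10.22 ± 0.93 with rosiglitazone and 16.61 ± 0.56 with vehicle (SD, n = 2 each). S100a9 had 10.05 ± 0.25 and 15.62 ± 0.21. Lcn2, the siderophore-binding lipocalin 2, fell at least 30.3-fold on the probe set named by the rule (limma, adjusted p = 0.00214), while another probe set of the same gene had a log2 fold change of -0.69 and did not pass (adjusted p = 0.516). Further falls past the threshold were those of Ccl3, Gadd45b, Wfdc21, Acod1, Arg1, Lilr4b, Il1rn, Slpi and Il1r2, with log2 fold changes from -4.45 for Ccl3 to -3.01 for Il1r2. Of these, both rosiglitazone arrays lay at the floor for the arginase Arg1, which fell at least 17.7-fold, and for Wfdc21, which fell at least 19-fold (log2 fold change -4.25). Il1rn and Il1r2, an antagonist and a decoy receptor of interleukin 1, fell 12.6-fold and 8.04-fold, and another probe set of Il1r2 had -2.07 and did not pass (adjusted p = 0.0744). The log2 fold change of Il1rn was -4.59 without rosiglitazone replicate 1 and -2.71 without rosiglitazone replicate 2. Slpi, a secreted inhibitor of leukocyte proteases, also fell on a further probe set (log2 fold change -2.28, adjusted p = 0.00422), while another had 0.47 and did not pass. Among the 23 lower probe sets, 7 had both rosiglitazone arrays at the floor and 4 had 1.

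**Figure D1:**
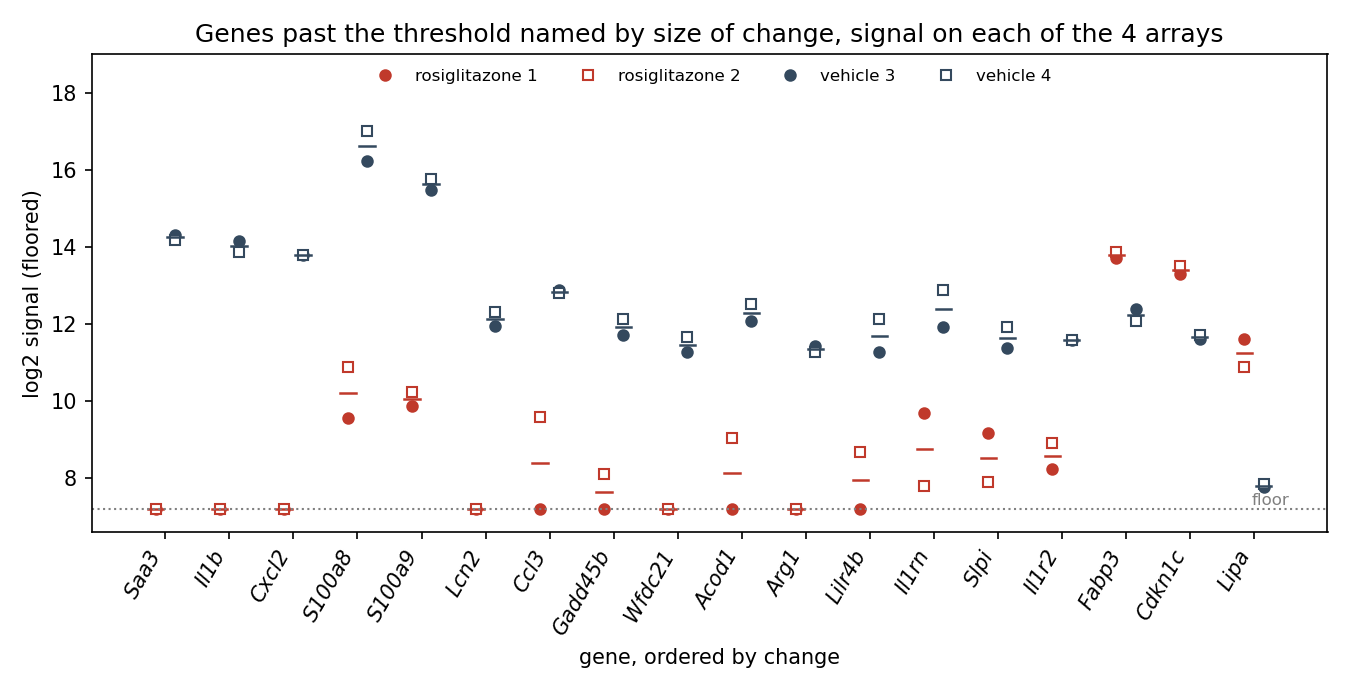
Log2 intensity, after the floor (dotted line), of the 18 genes past the threshold that were named by the size of their change, on each of the 4 arrays, with rosiglitazone arrays in red, vehicle arrays in dark blue, filled circles and open squares for the separate arrays of a group, and short bars for group means. For each gene both rosiglitazone arrays lie on the same side of both vehicle arrays, and those of Saa3, Il1b, Cxcl2, Lcn2, Wfdc21 and Arg1 lie at the floor.

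The list of inflammatory mediators was lower with rosiglitazone as a group. Of its 22 measured genes 17 had a fold change below 0, with a median log2 fold change of -0.66 (camera, adjusted p = 1.26e-07), but the call was lost with an estimated correlation (adjusted p = 0.135). On the probe set used for the list, Saa3, Il1b, Cxcl2 and Ccl3 passed the threshold over all probe sets and 18 genes did not, among them Lcn2, which passed on its other probe set. In this list 6 genes were lower adjusted over the list alone, the further genes being Nfkbia, the inhibitor of NF-κB that NF-κB itself induces (-1.09), and the chemokine Ccl9 (-1.37), both named after their values were seen. The 17 measured macrophage markers were lower too, with 16 below 0 and a median of -0.65 (camera, adjusted p = 1.73e-07), again lost with an estimated correlation (adjusted p = 0.135). Cd14, the co-receptor for lipopolysaccharide, fell 7.62-fold (log2 fold change -2.93, standard error 0.20, adjusted p = 1.45e-04) and was the only macrophage marker of 17 past the threshold. A total of 5 macrophage markers were lower adjusted over the list alone, with Laptm5 at -1.17, Tyrobp at -1.21 and Ctss at -1.09. Saa3, Il1b, Cxcl2, Ccl3 and Cd14 each lost their calls without vehicle replicate 3 and without vehicle replicate 4, although the falls stayed about as large, with log2 fold changes of -6.97 and -7.10 for Saa3, -4.41 and -4.49 for Ccl3 and -2.91 and -2.95 for Cd14. The fall of Ccl3 varied more with the rosiglitazone arrays, at -3.26 without rosiglitazone replicate 1 and -5.63 without rosiglitazone replicate 2. The erythrocyte markers, genes of red cells, were lower on the same arrays, with a median of -0.76.

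Immediate-early genes, which are transcribed within minutes of a stimulus, were lower as a group as well. Of 21 measured genes 19 lay below 0, with a median of -0.59 (camera, adjusted p = 1.99e-05), and the call was lost with an estimated correlation (adjusted p = 0.316). The median was -0.31 without rosiglitazone replicate 1. Macrophage, lymphocyte and erythrocyte markers were lower on the same arrays (medians -0.65, -0.65 and -0.76), while brown adipocyte markers were higher (0.51). Gadd45b, a growth arrest and DNA damage gene, fell 19.2-fold with 1 rosiglitazone array at the floor (adjusted p = 0.00768). A second probe set of Gadd45b had -2.19 and did not pass, and the Gadd45b call was lost without vehicle replicate 3 (log2 fold change -4.46) and without vehicle replicate 4 (-4.07). In total 5 were lower and 1 higher adjusted over the list alone, the lower ones including Ier3 at -2.42, Atf3 at -1.13 and Zfp36 at -1.66, the last at -0.93 without rosiglitazone replicate 1 and -2.40 without rosiglitazone replicate 2.

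Contractile genes of smooth muscle, the main cell type of the aortic wall, were lower with rosiglitazone. Of 18 measured genes 17 lay below 0, with a median log2 fold change of -0.78 (camera, adjusted p = 1.9e-10), and the call was lost with an estimated correlation (adjusted p = 0.135). Tagln, the actin-binding protein transgelin, fell 2.40-fold (log2 fold change -1.26, standard error 0.21, adjusted p = 0.0456 in limma) and was the only gene of the 18 past the threshold over all probe sets. Of the contractile genes 10 were lower adjusted over the list alone, with log2 fold changes of -1.33 for the calponin Cnn1, -1.55 for the smooth muscle myosin heavy chain Myh11 and -1.12 for the smooth muscle actin Acta2. Fibroblast and extracellular matrix genes were lower too, with 31 of 36 below 0 and a median of -0.53 (camera, adjusted p = 2.80e-06; adjusted p = 0.135 with an estimated correlation). Mgp, matrix Gla protein, an inhibitor of vascular calcification, fell 2.50-fold (adjusted p = 0.0394) and was the only gene of these 36 past the threshold. Among matrix genes 2 were lower adjusted over the list alone, the other being the collagen gene Col1a2 at -0.96, whose second probe set had 0.51. Neither Tagln nor Mgp passed with vehicle replicate 3 or vehicle replicate 4 left out, at -1.25 and -1.28 for Tagln and -1.43 and -1.22 for Mgp. Brown adipocyte markers, which belong to another cell type, were higher on the same arrays, with a median of 0.51.

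Genes of fatty acid use were higher with rosiglitazone as groups, by less per gene. The list of PPARγ target genes had 21 of 23 measured genes above 0 and a median log2 fold change of 0.52 (camera, adjusted p = 2.97e-10), a call lost with an estimated correlation (adjusted p = 0.135). None of them (0) passed over all probe sets in limma, and adjusted over the list alone 11 were higher. They included the glycerol channel Aqp7 (log2 fold change 1.49), the hormone-sensitive lipase Lipe (1.10), the lipoprotein lipase inhibitor Angptl4 (1.13) and the cytochrome P450 Cyp4b1 (0.91). These were the members with the smallest p. Fabp4 (-0.19), Cd36 (0.19) and Lpl (0.07), named after their values were seen, had overlapping groups and were not among the 11. Fatty acid beta-oxidation had 19 of 22 above 0 and a median of 0.42 (camera, adjusted p = 1.62e-06; adjusted p = 0.21 with an estimated correlation), with 0 past the threshold in limma either over all probe sets or adjusted over the list alone. Its members with the smallest p were Ech1 at 0.76, Cpt2 at 0.69, Etfdh at 0.73 and Hsd17b4 at 1.54, the last at 0.63 without rosiglitazone replicate 1 and 2.44 without rosiglitazone replicate 2. The tricarboxylic acid cycle and oxidative phosphorylation list had 37 of 41 above 0 and a median of 0.34 (camera, adjusted p = 1.73e-07; adjusted p = 0.135 with an estimated correlation). Of its genes 1 was higher adjusted over the list alone, Ogdh, a subunit of oxoglutarate dehydrogenase (1.28).

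Brown adipocyte markers, which overlap with these lists, had 10 of 11 measured genes above 0 and a median of 0.51 (camera, adjusted p = 1.05e-05; adjusted p = 0.16 with an estimated correlation). Fabp3 (adjusted p = 0.024 in limma) was the only brown adipocyte marker past the threshold and did not pass without vehicle replicate 3 (log2 fold change 1.70) or vehicle replicate 4 (1.39). Of these markers 3 were higher adjusted over the list alone, the others being the fatty acid receptor Ppara (0.90) and the uncoupling protein Ucp1 (0.98), whose intensities were 97800 and 73420 with rosiglitazone and 54980 and 33470 with vehicle. A second probe set of Ucp1 had a log2 fold change of 0.42 (adjusted p = 0.568). White adipocyte markers did not pass, with 5 of 15 above 0 and a median of -0.19 (camera, adjusted p = 0.692). Of these 15, Lipe was higher adjusted over the list alone and the others were not past it. Pparg itself, the receptor of the drug, had a log2 fold change of -0.58 with overlapping groups (adjusted p = 0.602 in limma), from -1.08 to -0.083 with 1 array left out.

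Lipa had intensities of 3103 and 1880 with rosiglitazone and 220 and 229 with vehicle (limma, adjusted p = 0.035). This call was lost with any of the 4 arrays left out, at log2 fold changes from 3.07 without rosiglitazone replicate 1 to 3.79 without rosiglitazone replicate 2. Cdkn1c had 10010 and 11660 with rosiglitazone and 3127 and 3363 with vehicle (adjusted p = 0.0153), and lost its call without vehicle replicate 3 (log2 fold change 1.68) and without vehicle replicate 4 (1.79). At an unadjusted p under 0.05 in limma, 1.5-fold and no overlap between the groups, 322 probe sets were higher with rosiglitazone, the 3 called ones among them. Of the rest, the naming rule took the 9 genes with the smallest unadjusted p, which did not pass the adjustment. They were Csad, Aatk, Uck1, Aqp7, Hcn2, Ephx2, Acaa1b, Cldn5 and Slc4a4, with log2 fold changes from 1.11 for the peroxisomal thiolase Acaa1b to 1.74 for the kinase Aatk and adjusted p from 0.0584 for Csad to 0.0799 for Slc4a4.

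Among markers of other blood cells, lymphocyte markers had 10 of 12 below 0 and a median of -0.65 (camera, adjusted p = 0.0164; adjusted p = 0.278 with an estimated correlation). No lymphocyte marker (0) passed over all probe sets, and adjusted over the list alone 1 was lower, the B-cell receptor component Cd79a (-2.03). Without rosiglitazone replicate 2 or vehicle replicate 3 the list did not pass (adjusted p = 0.055 and 0.0729), and the median was -0.31 without rosiglitazone replicate 1. Erythrocyte markers had 4 of 6 below 0 and a median of -0.76 (camera, adjusted p = 0.0277; adjusted p = 0.30 with an estimated correlation). Of the 6, 3 were lower adjusted over the list alone, Bpgm (-0.94), the haem synthesis enzyme Alas2 (-0.73) and the globin gene Hbb-b2 (-0.78), while the globin gene Hba-a1 had 0.02 and the anion exchanger Slc4a1 0.65, both named after their values were seen. That call was lost without rosiglitazone replicate 2, vehicle replicate 3 or vehicle replicate 4 (adjusted p = 0.055, 0.0747 and 0.0519), and the median was -0.50 without rosiglitazone replicate 1. Cell cycle genes had 14 of 16 below 0 and a median of -0.26 (camera, adjusted p = 0.0416; adjusted p = 0.335 with an estimated correlation), with 0 past the threshold in limma adjusted over the list alone. Pcna, the replication clamp, had -1.38 and the helicase subunit Mcm2 had -2.37. The cell cycle call was lost without rosiglitazone replicate 1 or vehicle replicate 3 (adjusted p = 0.262 and 0.16), and the median was -0.42 without rosiglitazone replicate 2.

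The remaining 12 lists did not pass in camera. Endothelial markers had a median of -0.32 (adjusted p = 0.437), with the tight junction gene Cldn5 at 1.45 and higher adjusted over the list alone. Vascular tone genes had a median of -0.09 (adjusted p = 0.245), with prostacyclin synthase Ptgis at -1.17 and lower adjusted over the list alone, and the potassium channel subunit Kcnmb1 at -2.86. Insulin and glucose handling had a median of 0.11 (adjusted p = 0.128), with 0 genes past the threshold in limma adjusted over the list alone. Circadian clock genes had a median of -0.30 (adjusted p = 0.14), with Dbp at -1.66 and Bhlhe40 at -2.75 (from -3.45 to -2.04 with 1 array left out), both lower adjusted over the list alone. Lipogenesis had a median of -0.05 that turned positive when each array was centred on its median (adjusted p = 0.884). Its members went both ways adjusted over the list alone, with 2 higher, Srebf1 (0.96) and Dgat1 (0.85), and 2 lower, Scd2 (-1.09) and Elovl6 (-1.02). Second probe sets gave smaller values, -0.03 for Dgat1, -0.34 for Scd2 and -0.47 for Elovl6, and did not pass over all probe sets. Redox and xenobiotic genes had a median of -0.04 that also turned positive on centring (adjusted p = 0.692), with Ephx2 (1.35) and Gsta2 (2.19) higher and Mt2 (-0.87) and Cyp2f2 (-1.45) lower adjusted over the list alone. The heat shock list had a median of -0.04 and a mean of -0.01, both against an upward direction in camera (adjusted p = 0.884), and its median too turned positive on centring. For lipogenesis the mean was 0.0027 and the camera direction upward, against the negative median. Cholesterol synthesis (median -0.31, adjusted p = 0.652), nerve and Schwann cell markers (0.19, adjusted p = 0.692), cardiac muscle markers (0.01, adjusted p = 0.692) and skeletal muscle markers (0.01, adjusted p = 0.884) had 0 genes past the threshold in limma adjusted over the list alone.

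**Figure D2:**
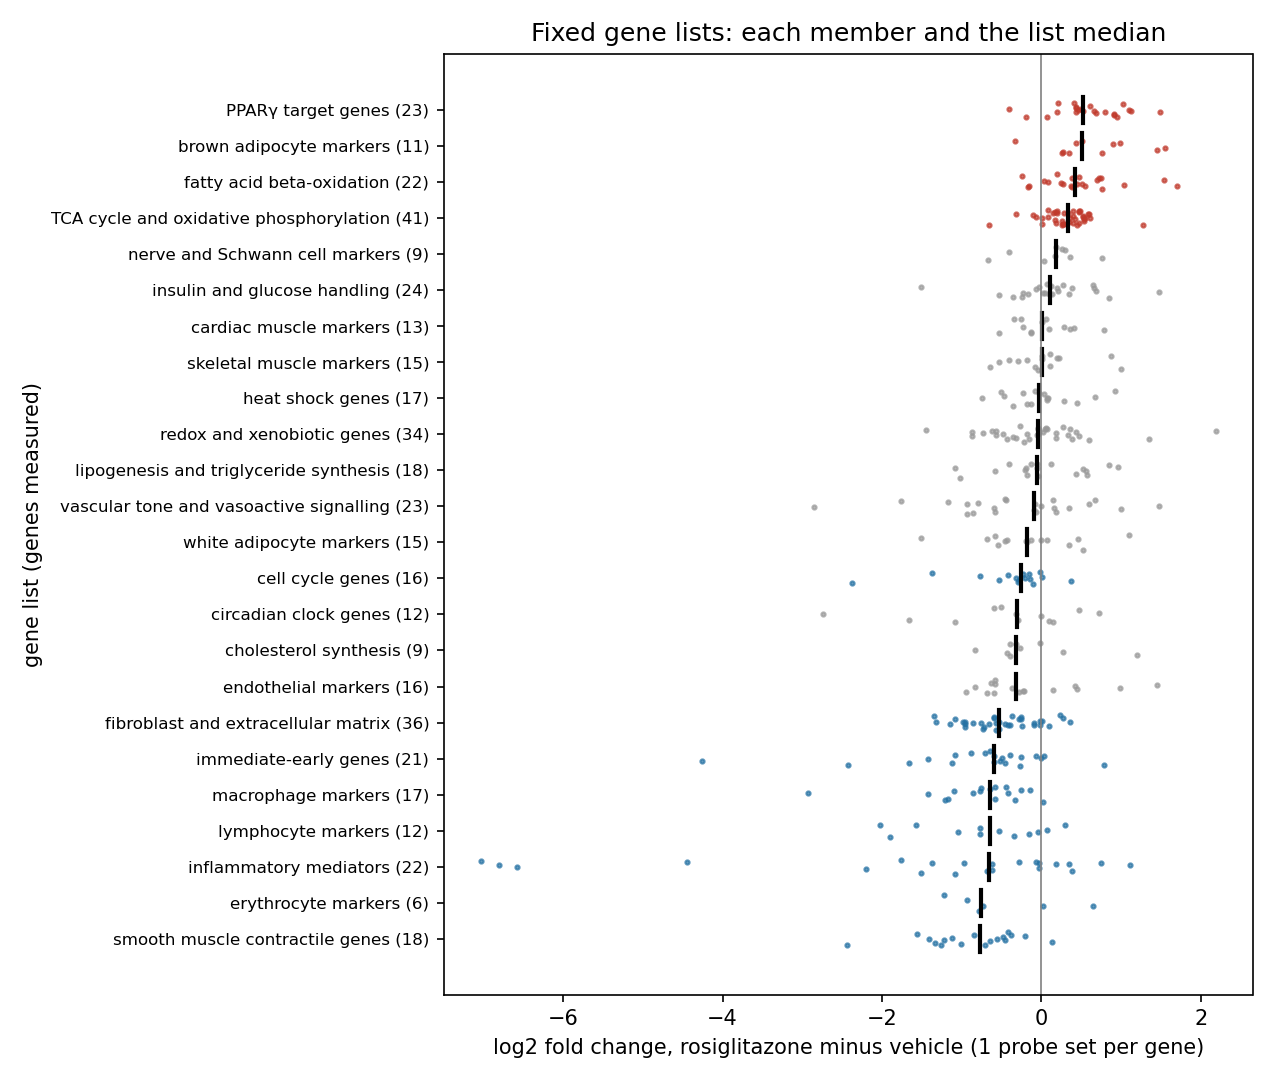
Log2 fold change, rosiglitazone minus vehicle, of each measured gene (points, 1 probe set per gene) in the 24 fixed lists, with the list median as a black bar and the number of genes measured in brackets. Lists that passed in camera at the preset correlation are red (4 with a median above 0) or blue (8 with a median below 0), and the other 12 are grey, with PPARγ target genes at the top (median 0.52) and smooth muscle contractile genes at the bottom (median -0.78).

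Across the 24 lists, 12 passed in camera, 4 higher and 8 lower, 0 of them with an estimated correlation, where 7 had an unadjusted p under 0.05. In fry, which does not compare a list with other genes, 7 passed. The lists past camera that did not pass in fry were fatty acid beta-oxidation (fry, adjusted p = 0.075), tricarboxylic acid cycle and oxidative phosphorylation (0.059), immediate-early (0.075), erythrocyte (0.056) and cell cycle genes (0.109). Of 432 different list genes measured, 9 passed over all probe sets in limma on the brightest probe set of the gene, and Lcn2 passed on another.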

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

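The rule for control probe sets, which asked for at least a 1.5-fold rise and no overlap between the groups, was chosen only after the other results were seen. Control probe sets of mouse transcripts were outside the tests above, where those of actin and Gapdh served only for the ratios of 3' to 5' signal. Of 23 such probe sets 3 met the rule, with both rosiglitazone arrays above both vehicle arrays. Chance gives no overlap, in either direction, for 33.3% of probe sets, so a lack of overlap in 3 of 23 shows no change by itself. A probe set for the 3' part of pyruvate carboxylase was 1.85-fold higher, with intensities of 13006 and 6485 against 5207 and 4753. A probe set for the middle part of the same transcript was 2.42-fold higher, at 963 and 216 against 206 and 173. A probe set for the 5' part of the transferrin receptor was 2.17-fold higher after the floor, at 295 and 619 against 262 and 35. Other control probe sets of these transcripts did not rise in this way: the 5' part of pyruvate carboxylase was at 0.845-fold and another middle part at 0.675-fold, and the transferrin receptor was at 1.27-fold for its 3' part and under the floor on every array for its middle part. The rule looked for rises only, and 1 of the 23 was lower by as much with no overlap, the control probe set named MurFAS, at 461 and 964 with rosiglitazone against 1251 and 1366 with vehicle (log2 fold change -0.97). The ordinary probe sets of the same genes did not pass in limma, with log2 fold changes of 0.60 and -0.05 for Pcx and -0.23 for Tfrc, genes looked up after their control values were seen. No explanation was tested for these control values.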

How the results depend on the processing

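The alternatives with lists reduced to genes in no other fixed list were chosen only after the data were seen. With 2 arrays per group and no detection calls, signal over background cannot be judged, and a group left with 1 array is assumed to vary like the other group. All 26 calls had the same sign in every setting in which they were tested. No paired analysis was possible because the groups share no replicate numbers.

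In place of 26 calls, 17 remained of these with centring on the median and 17 with the floor at the 5th percentile. There were 7 calls without a trend, 85 at an adjusted p of 0.10 and 718 at an unadjusted p under 0.05 with 1.5-fold and no overlap. With the floor at the 40th percentile and with no filter there were 0 calls in limma, with 933 and 1202 probe sets at an unadjusted p under 0.05. Both settings tested 12422 probe sets in place of 7134, with prior degrees of freedom of 0.854 and 1.07 in place of 7.14. They are not separate checks, because the filter lay at the same intensity of 414 and dropped nothing after that floor. With 1 array left out the count ran from 1 to 78. In place of 9 list genes past the threshold, on 1 probe set per gene, there were 5 with the floor at the 5th percentile, 0 with that at the 40th, 0 with no filter, 3 without a trend and 0 to 22 with 1 array left out. Of the 22, found without rosiglitazone replicate 2, 9 were the same genes. The other 2 of the 3 splits of the arrays gave 0 calls and 0 lists, with 245 and 159 probe sets at an unadjusted p under 0.05. These 3 splits are too few for a share under 0.05. The S100a9 call held in 12 of 14 settings and that of Lipa in 5 of 14.

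Of 12 lists past the threshold, 0 passed with an estimated correlation and 7 in fry. The estimate lay under the preset 0.01 for smooth muscle (-0.018), PPARγ target (-0.017), inflammatory (-0.035), macrophage (-0.031), matrix (-0.028), lymphocyte (-0.062) and erythrocyte genes (-0.13). It lay above for immediate-early (0.17), beta-oxidation (0.069), cell cycle (0.026), brown adipocyte (0.019) and respiratory genes (0.013). So a higher correlation did not lose the former calls. With an estimate, camera's test has only the 2 residual degrees of freedom. Under the estimated correlation the medians stay as they were and the p-values alone change: 0.52 for PPARγ targets, 0.51 for brown adipocyte, 0.42 for beta-oxidation, 0.34 for respiratory, -0.78 for smooth muscle, -0.53 for matrix, -0.66 for inflammatory, -0.65 for macrophage, -0.65 for lymphocyte, -0.76 for erythrocyte, -0.59 for immediate-early and -0.26 for cell cycle genes. With no filter, lymphocyte (-0.34) and erythrocyte markers (-0.73) lost their calls, and erythrocyte markers (-0.76) did so without a trend. Cell cycle genes lost theirs with quantile normalisation (-0.20), with the floor at the 40th percentile (-0.11) and with the filter at the 60th (-0.29). With 1 array left out, medians ran from -0.50 to -0.31 for lymphocyte, from -0.80 to -0.50 for erythrocyte and from -0.42 to -0.29 for cell cycle genes. The medians without shared members were 0.67 for 16 PPARγ targets, -0.53 for 35 matrix genes and 0.94 for 6 brown adipocyte markers, all past the threshold. The cause of the other changes was not tested.

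Reversals occurred in results that had not passed. With each array centred, lipogenesis had 0.032, heat shock genes 0.048 and redox genes 0.041. The filter at the 60th percentile gave 0.027 for heat shock and -0.038 for skeletal muscle, the pseudocount -0.017 for skeletal muscle, and the mean of probe sets -0.12 for cardiac muscle. With 1 array left out, lipogenesis ran from -0.19 to 0.071 and skeletal muscle from -0.14 to 0.080. Sqle ran from -0.36 without vehicle replicate 4 to 2.78 without vehicle replicate 3, Car2 from -3.05 without rosiglitazone replicate 1 to 0.59 without rosiglitazone replicate 2, and Hspe1 from -0.069 without rosiglitazone replicate 1 to 1.92 without rosiglitazone replicate 2. The cause of these reversals was not tested.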

Other observations

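The tests of erythrocyte, white adipocyte, brown adipocyte, endothelial and matrix genes below were chosen only after the results were seen. The neutrophil, peroxisomal, NF-κB and hypoxia lists were written after the fixed lists had been examined and before their own values were looked up, and the members named from them below were picked after their values were seen.

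Genes of peroxisomes, organelles that shorten very long fatty acids, were higher on the rosiglitazone arrays beyond the fixed lists. Of 21 measured peroxisomal genes in no fixed list 18 lay above 0, with a median log2 fold change of 0.47 (bootstrap 95% interval over genes 0.26 to 0.64; camera, adjusted p = 2.2e-04 over these 4 lists; unadjusted p = 0.079 with an estimated correlation). They included the fatty acid transporters Abcd2 at 1.67 and Abcd3 at 0.64 and malonyl-CoA decarboxylase Mlycd at 0.84, while the amino acid oxidase Dao had -1.15. A further 10 of the 31 measured peroxisomal genes were in fixed lists, and 26 of the 31 lay above 0. Brown adipocyte markers were higher on the same arrays (median 0.51), and white adipocyte markers were not (median -0.19). Genes are not independent replicates, so these intervals cover the spread over genes and not over animals.

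NF-κB inducible genes outside the fixed lists and not past the threshold had a median of 0.15 over 11 genes (interval -1.05 to 0.30; camera, unadjusted p = 0.477, and 0.534 with an estimated correlation), from Birc3 at -1.64 to Nfkbie at 0.96. All 31 measured genes of that list had a median of -1.05, with 23 below 0. The 11 are what was left after 18 in fixed lists and 8 past the threshold, some of them both, were taken out, so their median decides nothing about the list. Hypoxia inducible genes outside the fixed lists had a median of -0.049 over 14 genes (interval -0.69 to 0.25; camera, unadjusted p = 0.47, and 0.523 with an estimated correlation), with Ddit4 at -1.84 and Egln1 at 0.74, which does not tell whether they moved as a group.

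A few probe sets past the threshold lay outside the naming rule and are named here after their values were seen. Basp1 fell 7.09-fold, Ogn 4.40-fold and Serpina3n, an acute-phase protease inhibitor, 5.06-fold, and a probe set with no listed gene fell at least 22.9-fold with both rosiglitazone arrays at the floor. Other probe sets of Basp1 and Ogn had log2 fold changes of 0.02 and 0.09.

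The falls of neutrophil-associated and inflammatory genes could come from fewer neutrophils in the rosiglitazone pools, more blood left in the vehicle pools, or lower expression under the drug. A difference between the pooled animals apart from the drug could give this and the other patterns too. The labels do not say whether the arrays of a group came from separate pools, so such a difference cannot be told apart from the drug. More blood of like make-up in the vehicle pools is argued against as the whole cause of the falls past the threshold. Erythrocyte markers had a median of -0.76 (interval -1.08 to 0.33), far from the median of -6.39 over the 7 inflammatory and neutrophil genes called lower on any probe set. Those 7 were picked by their falls on these same arrays, and only 6 erythrocyte genes were measured. Blood richer in neutrophils is not covered by this comparison. For the inflammatory and neutrophil genes as a group, blood cannot be told apart from the other explanations. The median of all 43 measured minus the erythrocyte median was 0.069 (interval -1.12 to 0.47), on the brightest probe set of each (another than the called one for Lcn2). Fewer neutrophils cannot be told apart from lower expression of these genes: 19 neutrophil markers that had not passed had a median of -0.67 (interval -1.10 to -0.10; camera over these 19, unadjusted p = 2.2e-05, and 0.0439 with an estimated correlation), between the bounds set for either outcome, and all 21 measured had -0.81. S100a8 and S100a9 had log2 intensities of 16.21 and 17.01 and of 15.47 and 15.76 with vehicle, Mmp9 had -2.80 and Ltf had 0.12, and how many of the markers the aorta itself expresses was not examined. An effect of the drug within cells stays open and was not tested.

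The lower smooth muscle genes could reflect a smaller share of smooth muscle, less vessel wall against fat, or lower expression under the drug. A smaller share of smooth muscle with all other cell types raised alike cannot be judged from these lists. Brown adipocyte and endothelial medians differed by 0.83 (interval 0.34 to 1.48), but the drug may raise brown adipocyte markers within cells. Of these markers, 5 of 11 are also in other fixed lists. Endothelial markers, which such a shift would raise, had a median of -0.32 and did not pass in camera. Less vessel wall against fat cannot be told apart from lower expression of these genes. Matrix genes were lower too (interval of their median -0.66 to -0.28) and the smooth muscle median minus the matrix median was -0.25 (interval -0.76 to 0.084). But the white adipocyte median of -0.19 (interval -0.46 to 0.34) neither shows nor excludes a small rise of fat. Brown adipocyte markers were higher, with 10 of 11 above 0 and a median of 0.51. More brown fat or induction by the drug could give that, and these arrays do not part them. Lower expression per cell under the drug stays open and was not tested.

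The higher fatty acid oxidation and respiratory genes may come from more fat in the rosiglitazone pools, from a larger share of brown against white fat, or from induction by the drug. More fat, white and brown alike, would raise white adipocyte markers by about as much, unless the drug lowers them within cells. The white adipocyte median minus that of fatty acid beta-oxidation was -0.60 (interval -0.98 to -0.17). This argues against more fat as the whole cause only if the drug leaves white adipocyte markers unchanged within cells, which was not tested. A smaller rise of fat is not excluded by this. A larger share of brown fat stays open, because 7 brown adipocyte markers outside the PPARγ target, oxidation and respiratory lists had a median of 0.90 (interval 0.27 to 1.45), and brown minus white medians gave 0.69 (interval 0.27 to 1.34). Induction of these genes within cells by the drug would raise them as well, and these arrays hold no test that parts it from a change in cell types.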
